A study of Mus musculus with 2 samples.

How the data were processed

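Single cell RNA-seq was measured in cerebral cortex of newborn (postnatal day 0) C57BL/6 mice, digested to single cell suspensions and captured in droplets, per the labels' protocols. The design text speaks of triplicates, and 1 library of each of 2 genotypes was analysed here: wild type (WT) and FOXM1f/+;Nestin-Cre. The groups were taken from the genotype labels. The labels do not spell out what the FOXM1 allele holds, and the series title names the human gene.

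The authors deposited, per library, a sparse matrix of UMI counts per gene and cell without normalization, per the file headers and the whole-number values, and a cell table with total UMI counts and detected genes. The submitters' processing notes name STAR, Cell Ranger version 2, Seurat and the genome build mm9, while the matrix headers give the software version 3.0.1. Of 51912 features, 51719 have their identifier in the GENCODE M21 annotation of GRCm38, 193 do not, and 0 belong to a human gene. Transcripts of a human FOXM1 allele were therefore not counted as a feature of their own, and the counts of mouse Foxm1 do not check the genotype label. The authors' deposited table of cluster markers has 32126 rows for 25 clusters. It gives a log fold change (taken as natural log from the column name, since the base is not stated), the fraction of cells with the gene in a cluster, and a p-value over cells, per the file headers. That table compares clusters, not genotypes. A matrix that pools both libraries was not used, because its cell table does not map cells to samples.

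Cells were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells, and called doublets were left out. The automatic threshold marked 2.28% of the WT and 2.37% of the FOXM1f/+;Nestin-Cre cells, where 6.85% and 6.03% were expected. Both libraries were clustered together without batch integration: counts per cell scaled to 10000, log transformed, 2000 variable genes, values clipped at 10, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0). This gave 32 clusters. A cluster was named after the class with the most of its markers among the 50 leading genes by fold. It needed at least 3 detected markers of that class, and not more markers of another class among its 10 leading genes. Under these rules 24 clusters fell into 15 classes, each called "like" its type, and 8 stayed unnamed. The unnamed clusters held 21.1% of the WT and 20.6% of the FOXM1f/+;Nestin-Cre cells. All names are rebuilt from markers and may differ from the authors' own.

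Cells are not replicates, and 1 library per genotype allows no test, so no p-value, standard error or count of changed genes is given. UMIs were summed over the kept cells of each library, whole and per class, and given as CPM (UMIs of a gene scaled to 1e6 in total) with exact Poisson 95% intervals. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals, and log2 ratios (FOXM1f/+;Nestin-Cre over WT) exact conditional binomial intervals. These intervals cover counting error only, not the spread between mice or between captures. Intervals of a median over genes come instead from ranking or resampling the genes as if independent. They do not cover the spread between mice or captures either. Against 0 counts a ratio is given as a bound with a floor of 3 UMIs over the class. Expression was compared in the 8 classes with at least 200 kept cells in each library, and in cluster 9, an unnamed cluster of dividing cells. Cluster 9 was added as a unit after the data were seen.

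The filters, comparisons, gene lists, markers and naming rules were fixed before the data were examined. The named genes of the whole library were the 10 with the highest and the 10 with the lowest log2 ratio among genes with a mean CPM of at least 20 and at least 200 UMIs. Per class they were the 5 highest and 5 lowest with a mean CPM of at least 20 and at least 100 UMIs. Per list they were the 2 members with the highest CPM and the 2 with the largest ratio among those with at least 50 UMIs. Foxm1 and Lin28a were always included, and some genes that these rules name are not reported here. The 22 gene lists covered FOXM1 target genes, S phase, G2 and M phase, cell cycle inhibitors, the Lin28 and let-7, Notch, Wnt, Hedgehog and p53 pathways, outer radial glia genes, neuronal maturation and synapse, immediate early and dissociation genes, glycolysis, hypoxia, interferon, ER stress, cholesterol synthesis, mitochondrially encoded genes, ribosomal proteins, hemoglobins, nuclear oxidative phosphorylation genes and sex-linked check genes. For each list the members with at least 20 UMIs were counted as at least 1.25-fold higher, at least 1.25-fold lower or between. The median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these 2 libraries only.

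Cells with UMIs of at least 3 genes of the G2 and M phase list, or of the S phase list, were counted after each cell was thinned to 2000 UMIs, with shallower cells left out. A second count used at least 2 of 8 genes seen mainly in dividing cells (Top2a, Mki67, Cdk1, Nusap1, Ube2c, Birc5, Tpx2 and Cenpf) and was added after the data were seen. Sequence shared between genes was measured as 31-base words found in the transcripts of both, and 100 or more words were counted as sharing.

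The method was tested on Poisson counts simulated from the real means, with 200 genes changed by known folds. The intervals assume such counts, and no spread between cells, mice or captures was simulated. Coverage near 95% was thus built in, and the test checks the calculation only. Of 71 genes set 1.25-fold apart in the whole library, 100% came out in the right direction, with a median size of 0.32 against a true 0.33 on the log2 scale. The intervals held the true value for 94.4% of them. In radial glia-like cells 98.3% of 60 such genes had the right direction, and in cluster 9 96.6% of 59. A simulated list of 20 unchanged genes reached percentile 95.3 in cluster 9 at a median of 0.04, so a high percentile alone can come with a ratio near 0.

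Alternatives covered the cell filter, doublets, clustering resolution, scaling, weighting of cells, minimum counts, matching of the random lists and thinning. Settings added after the data were seen left cell cycle genes, or the 20 leading genes of 1 cluster, out of clustering, weighted the upper layer-like clusters alike, or took ribosomal protein genes without pseudogenes and S6 kinases. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots Matplotlib 3.10.9.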

Results

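The data were UMI counts from newborn mouse cortex, with 1 WT and 1 FOXM1f/+;Nestin-Cre library. Nestin-Cre is a recombinase line active in neural progenitors. The WT library held 10084 barcodes with 86579798 UMIs, and the FOXM1f/+;Nestin-Cre library 8796 barcodes with 84017466 UMIs. After filtering, 8368 WT cells with 80080513 UMIs (median 7805.5 per cell) and 7359 FOXM1f/+;Nestin-Cre cells with 77938988 UMIs (median 8936) were kept. Mitochondrial UMIs made up a median 3.19% in both, and ribosomal protein UMIs 8.73% in WT and 9.79% in FOXM1f/+;Nestin-Cre cells. There were no replicates, so each difference below has no replicate check and compares these 2 libraries.

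The first comparison asked how much Foxm1 each library held. Mouse Foxm1, a forkhead transcription factor that drives genes of G2 and mitosis, was at a like level in both by summed UMIs. It had 852 UMIs (10.6 CPM) in WT and 795 UMIs (10.2 CPM) in FOXM1f/+;Nestin-Cre cells, a log2 ratio of -0.06 (95% interval -0.20 to 0.08), but -0.27 when every cell was weighted equally. Most of these UMIs lay in the cluster of dividing cells, cluster 9, with 599 UMIs (114 CPM) in WT and 569 UMIs (119 CPM) in FOXM1f/+;Nestin-Cre cells, a log2 ratio of 0.06 (-0.11 to 0.23). Intermediate progenitor-like cells, which give rise to cortical excitatory neurons, had 63 UMIs (120.5 CPM) in WT and 56 UMIs (105 CPM) in FOXM1f/+;Nestin-Cre cells. In cluster 9, 69.8% of WT and 75.4% of FOXM1f/+;Nestin-Cre cells had a Foxm1 UMI, at median depths of 11897 and 14715 UMIs. Thinned to 2000 UMIs, with 7 WT and 4 FOXM1f/+;Nestin-Cre cells left out, these shares were 22.1% and 18.3%. The background was 1.17% and 1.40% in upper layer-like neurons, which have left the cell cycle, at median depths of 11909 and 12565.5 UMIs. Reads from a human FOXM1 transcript could only have been counted here where they align to the mouse gene. Lin28a, an RNA-binding protein that blocks let-7 processing, had 2 UMIs in WT and 4 in FOXM1f/+;Nestin-Cre cells, a log2 ratio of 1.04 (-1.76 to 4.51).

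**Figure D1:**
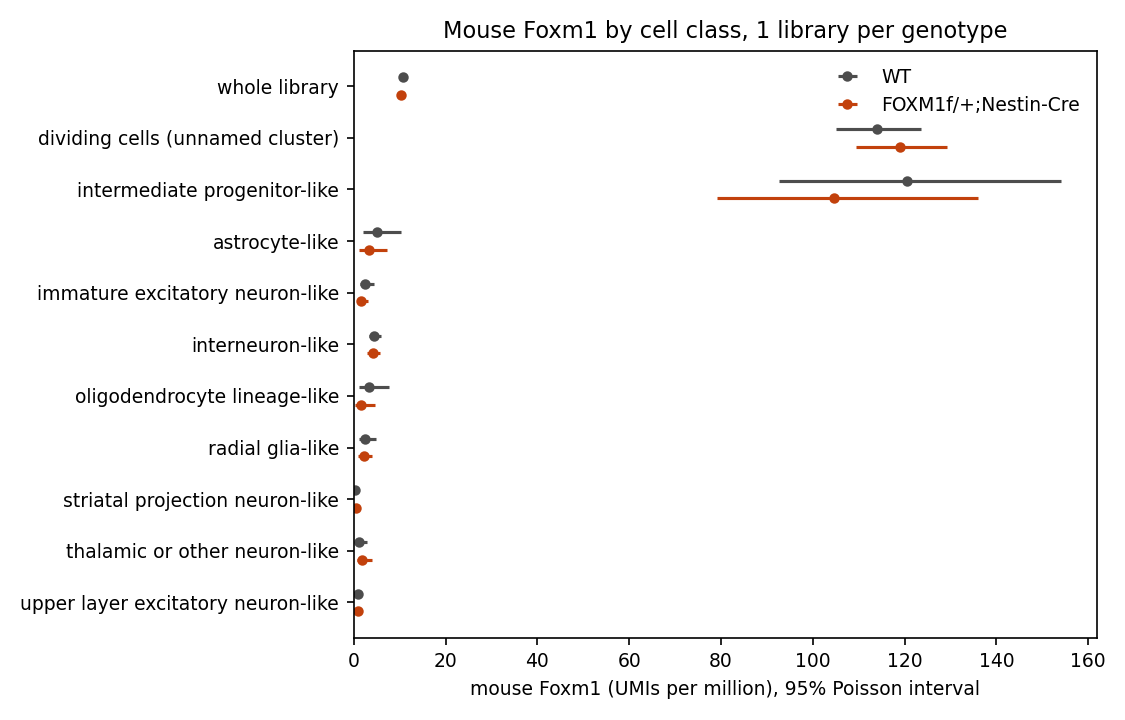
Mouse Foxm1 in CPM (x axis) by cell class (y axis), with 95% Poisson intervals, 1 library per genotype. The cluster of dividing cells and intermediate progenitor-like cells stand above 100 CPM in both libraries, and the intervals of the 2 libraries overlap in each class.

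The next comparison asked which cell classes differed in their share of cells. Cells like radial glia, astrocytes and the oligodendrocyte lineage were higher in the FOXM1f/+;Nestin-Cre library. Radial glia-like cells, named after the neural stem cells of the developing cortex, made up 5.16% of WT and 6.67% of FOXM1f/+;Nestin-Cre cells (432 and 491 cells). The log2 ratio was 0.37 (0.18 to 0.56). This name was a close call, with 7 radial glia and 6 astrocyte markers among the leading genes of the cluster. Astrocyte-like cells were at 2.49% and 3.30% (0.41, 0.14 to 0.68), and cells like the oligodendrocyte lineage at 2.55% and 3.33% (0.39, 0.12 to 0.66). Immature excitatory neuron-like cells were at 9.09% and 10.6% (0.22, 0.08 to 0.37), and striatal projection neuron-like cells at 8.88% and 10.2% (0.20, 0.05 to 0.35). Upper layer excitatory neuron-like cells were lower, at 17.4% of WT and 14.6% of FOXM1f/+;Nestin-Cre cells, a log2 ratio of -0.25 (-0.37 to -0.14).

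Within the upper layer-like class the clusters differed. Cluster 1, led by Nrgn, Inhba and Rorb, a nuclear receptor typical of layer 4, had 608 WT and 364 FOXM1f/+;Nestin-Cre cells, a log2 ratio of shares of -0.55 (-0.75 to -0.36). At a finer resolution a like cluster was named deep layer-like, so the layer of these cells is uncertain. Cluster 5, led by Inhba, Lpl and Mef2c, had 233 and 102 cells (-1.01, -1.36 to -0.66). Cluster 10, led by Hs6st2 and Jakmip1, went the other way with 614 and 608 cells (0.17, 0.01 to 0.34). Clusters 1 and 10 thus held most upper layer-like cells in WT, and cluster 10 alone in FOXM1f/+;Nestin-Cre. Unnamed cluster 17, led by Cbln2 and Grp, was also lower, at 3.81% and 2.39% (-0.67, -0.95 to -0.40).

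Cajal-Retzius cell-like neurons, the earliest cortical neurons and a source of reelin, were at 1.14% and 0.734% (-0.63, -1.14 to -0.13). The class named thalamic or other neuron-like, led by Neurod1, Calb2, Lhx9 and Prox1, was at 4.04% and 3.22% (-0.33, -0.57 to -0.08). Interneuron-like cells were at 22.1% and 20.9% (-0.08, -0.18 to 0.02). The intervals also held 0 for deep layer-like neurons (-0.25), ependymal or choroid plexus-like (-0.29), microglia-like (0.20) and intermediate progenitor-like cells (-0.28). The sizes of endothelial-like, mural-like and unnamed clusters 26 and 27 are not compared, since their leading genes differed between the libraries. Under a stricter cell filter the upper layer-like ratio was 0.0018, with other clusters counted in the class, among them 1 led by Tshz2 and Cck. Shares also move with dissection and capture, which the labels do not describe per mouse, and cells like striatal neurons lie outside the cortex proper.

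**Figure D2:**
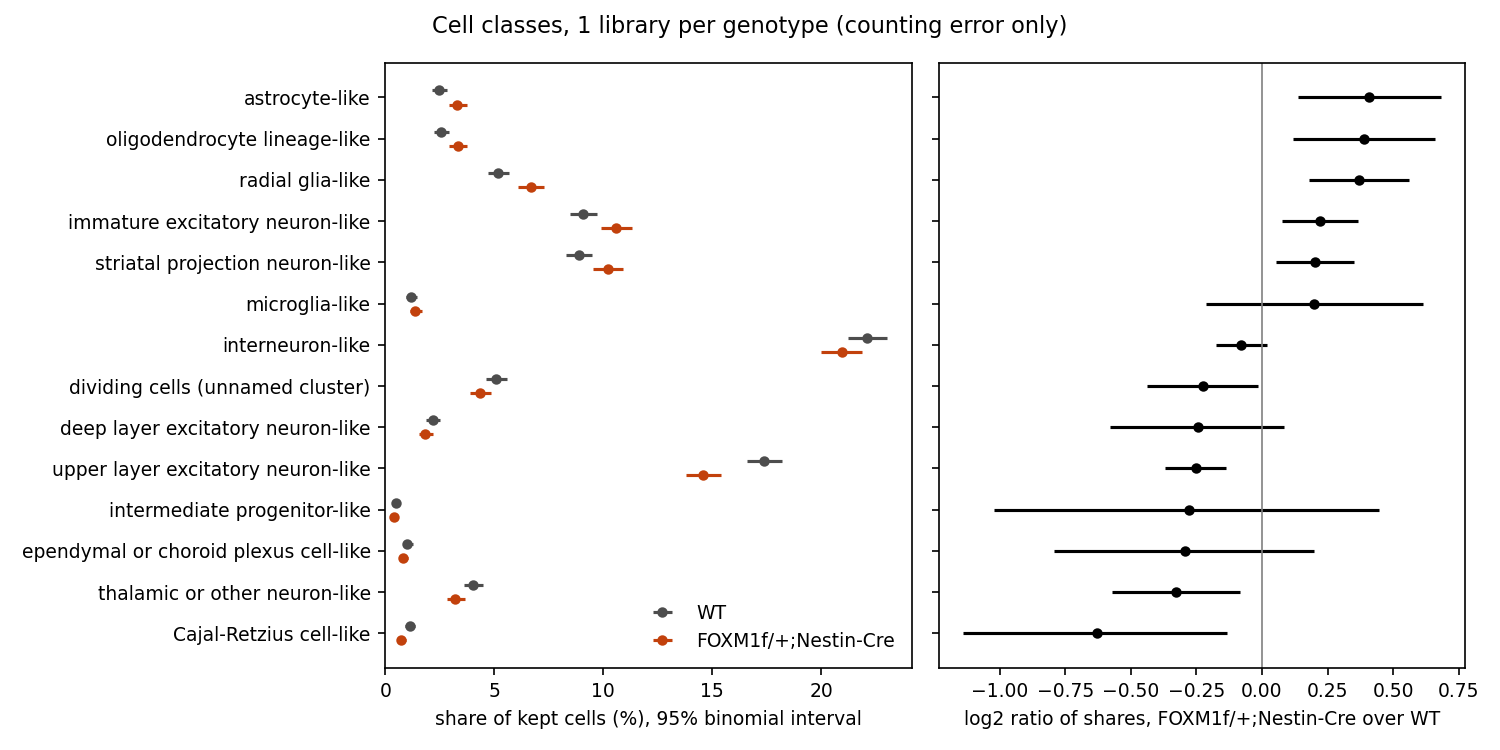
Left, share of kept cells (%) of each class in the WT and FOXM1f/+;Nestin-Cre libraries with 95% binomial intervals. Right, the log2 ratio of the shares with its interval. Astrocyte-like, oligodendrocyte lineage-like and radial glia-like cells lie between 0.37 and 0.41, and Cajal-Retzius cell-like neurons at -0.63.

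The whole-library comparison asked which genes and pathways differed. The list of 25 FOXM1 target genes was slightly lower in the FOXM1f/+;Nestin-Cre library, with a median log2 ratio of -0.19 (0 members higher past the fold limit set for lists, 2 lower). Its percentile among matched random lists was 0. Top2a, the topoisomerase that untangles chromosomes before mitosis, was at 163 and 141 CPM in WT and FOXM1f/+;Nestin-Cre cells (log2 -0.21). Hmmr, a spindle protein, was at 20.9 and 16.6 CPM (-0.33), and Ccnd1, the G1 cyclin D1, at 54.3 and 34.6 CPM (-0.65). Cenpb, a centromere protein, was at 141 and 139.5 CPM (-0.01). The G2 and M phase list had a median of -0.19 (0 of 51 higher, 2 lower, percentile 0), with Hmgb2 at 513 and 484 CPM (-0.09) and the kinetochore gene Ndc80 at 10.5 and 8.37 CPM (-0.33). The FOXM1 target and the G2 and M phase lists share members, such as Hmmr, so they are not separate results. Their members move together with the share of dividing cells, which was lower in cluster 9 (-0.23). Random lists were matched on expression only, so percentile 0 does not tell a shift in cell mix from one in expression. The S phase list was at -0.02 (0 of 42 higher, 0 lower, percentile 52.3), with Nasp at 191 CPM in both. Cell cycle inhibitors were at -0.01 (1 of 11 higher, 0 lower), with Cdkn2b at 0.48 on 147 and 199 UMIs.

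Genes of glial progenitors were higher. The outer radial glia list had a median of 0.33 (8 of 15 higher, 0 lower, percentile 100), with the lipid-binding protein gene Fabp7 at 937 and 1194 CPM (0.35), the glutamate transporter Slc1a3 at 240.0 and 351 CPM (0.55) and the matrix protein Tnc at 34.6 and 50.7 CPM (0.55). The Notch pathway list was at 0.32 (6 of 14 higher, 0 lower, percentile 100), with the effectors Hes1 (29.1 and 42.8 CPM, 0.56) and Hes5 (70.9 and 94.8 CPM, 0.42). The Wnt list was at 0.21 (5 of 17 higher, 1 lower), with the transcription factor Tcf7l2 at 0.64, and the Hedgehog list at 0.16 (3 of 10 higher, 0 lower), with Gli1 at 0.52 and Gli3 at 0.42. Inside radial glia-like cells the outer radial glia list was at 0.10 and the Notch list at 0.20. How far the shares of cells account for the whole-library values was not tested. Markers of radial glia (0.36) and astrocytes (0.35) were higher by a like amount, and markers of Cajal-Retzius cells (-0.43) and upper layer neurons (-0.18) lower.

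Neuronal and sterol genes were lower. The neuronal maturation and synapse list had a median of -0.17 (0 of 27 higher, 4 lower, percentile 0), with the microtubule regulator Stmn2 at 1852 and 1416 CPM (-0.39) and the syntaxin Stx1a at 57.5 and 42.5 CPM (-0.43). Cholesterol synthesis was at -0.20 (0 of 15 higher, 1 lower, percentile 0), with Hmgcs1 at 541 and 449 CPM (-0.27). Ribosomal protein genes were at 0.15 (49 of 192 higher, 13 lower, percentile 100), with Rpl23 at 0.16. Pseudogenes can take reads of their parent gene, so single members are uncertain.

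The remaining lists lay closer to 0 or rested on few members. Immediate early and dissociation genes were at 0.12 (4 of 20 higher, 1 lower), with the transcription factor genes Klf2 at 0.82 and Klf4 at 0.68. The p53 list was at -0.10 (1 of 14 higher, 1 lower), glycolysis at -0.03 (1 of 16 higher, 0 lower), the hypoxia list at 0.09 (0 of 12 higher, 2 lower) and the interferon list at -0.01 (2 of 15 higher, 2 lower). ER stress was at 0.05 (2 of 13 higher, 0 lower) and nuclear oxidative phosphorylation at 0.01 (1 of 89 higher, 1 lower). The Lin28 and let-7 list was at 0.03 (2 of 10 higher, 1 lower). Its member Hmga1 had 78 and 598 UMIs (2.98), but shares sequence with near-identical copies and is uncertain. Mitochondrially encoded genes were at -0.07 (3 of 30 higher, 9 lower). Among them mt-Atp8 was at 348 and 196 CPM (-0.83) but overlaps mt-Atp6, and mt-Cytb at -0.01, a sign that flipped with other scalings. All 4 measured hemoglobin genes were lower, with a median of -1.82 and Hbb-bs at 335 and 91.3 CPM (-1.88). Hemoglobin counts depend on the cell filter: with no filter the median was -0.94. In the striatal-like class the list was at 5.44, but with no filter its member Hba-a1, at 4.83 there, was at -0.23. Of the sex-linked check genes only Xist (137492 and 144932 UMIs) and its antisense partner Tsix were measured.

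Single genes with the largest ratios in the whole library fell into a few kinds. The highest was the pseudogene Gm12892 (0.375 and 55.2 CPM, log2 7.20) and the lowest were the ribosomal pseudogenes Rpsa-ps10 (594 and 14.5 CPM, -5.36) and Rpl14-ps1 (104 and 7.01 CPM, -3.90). These pseudogenes share 31-base words with Ckb, Rpsa and Rpl14, so their levels are uncertain. The same holds for Gm9825 (-0.93), Gm12166 (-0.91), Gm8186 (0.86) and the kinase gene Nme2 (41.2 and 19.8 CPM, -1.05). Genes higher in the FOXM1f/+;Nestin-Cre library were the neuropeptide Nts (28.7 and 66.0 CPM, 1.20), the prostaglandin synthase Ptgds (14.8 and 31.1 CPM, 1.07), the matricellular genes Ctgf (24.6 and 47.4 CPM, 0.95) and Cyr61 (41.2 and 69.6 CPM, 0.76), the peptide transporter Slc15a2 (20.1 and 37.9 CPM, 0.92), the glial filament gene Gfap (16.7 and 30.6 CPM, 0.88) and Pdxdc1 (0.75). Over 7439 genes with a mean CPM of at least 20 the median ratio was -0.01, and the 5th and 95th percentiles were -0.24 and 0.21.

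The cycling comparison asked whether more cells were dividing. The cluster of dividing cells was slightly smaller in the FOXM1f/+;Nestin-Cre library, at 4.36% against 5.10% in WT (321 and 427 cells, log2 -0.23, -0.44 to -0.01). Its leading genes are those of mitosis and had a median ratio of -0.15, so this size is not independent of the gene list. At 2000 UMIs per cell, 45.5% of 7785 WT and 43.9% of 6855 FOXM1f/+;Nestin-Cre cells had at least 3 G2 and M phase genes (-0.05, -0.12 to 0.02), with 583 and 504 cells left out. Unthinned, the shares were 89.3% and 90.6%. For S phase genes the shares at 2000 UMIs were 26.2% and 25.6% (-0.03, -0.12 to 0.06). Unthinned S phase shares were 80.7% and 83.8% (0.054, 0.0044 to 0.10). Deep layer-like neurons, which no longer divide, also met the G2 and M measure in 33.0% and 28.9% of cells, so it is not specific to dividing cells. With at least 2 of 8 genes seen mainly in dividing cells, 7.66% of WT (596 cells) and 6.35% of FOXM1f/+;Nestin-Cre cells (435 cells) were counted (-0.27, -0.45 to -0.09), and unthinned 10.7% and 10.4%.

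Within cluster 9, the dividing cells, the FOXM1 target list had a median of -0.15 (0 of 25 higher, 1 lower, percentile 0) and the G2 and M phase list -0.11 (0 of 51 higher, 1 lower, percentile 0). Ribosomal protein genes were higher in these cells at 0.24 and ER stress genes at 0.27 (6 of 13 higher, 0 lower), while immediate early and dissociation genes were at -0.27. Ccnd1 was at 103 and 63.6 CPM (-0.69, -0.90 to -0.49). Many members of the first 2 lists also define the cluster.

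Within radial glia-like cells, the transcription factor gene Zic4 was at 23.2 CPM in WT and 51.9 CPM in FOXM1f/+;Nestin-Cre cells (log2 1.16, 0.78 to 1.56) and carbonic anhydrase Car2 at 55.2 and 110.2 CPM. Arid5a (0.84) and Spata13 (0.79) were also higher. Neuronal genes were lower in these cells, with the transcription factor Mef2c at 192 and 65.8 CPM (-1.54), Arpp21 at 33.9 and 8.33 CPM (-2.02) and the synapse list at -0.35. Neuronal UMIs in glial cells can be free RNA or unmarked doublets. FOXM1 target genes were at 0.25 (8 of 17 higher, 1 lower, percentile 99.6), but at 0.04 over members with at least 100 UMIs. Unthinned, 16 WT (3.70%) and 36 FOXM1f/+;Nestin-Cre cells (7.33%) of this class had at least 2 of the 8 dividing genes (0.99, 0.10 to 1.93), at median depths of 7141 and 9095 UMIs. At 2000 UMIs 3 and 2 cells did. The Notch list was at 0.20 (2 of 13 higher, 0 lower) and immediate early and dissociation genes at -0.39.

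Within astrocyte-like cells the S phase list was at 0.34 (16 of 29 higher, 1 lower, percentile 100), the Wnt list at 0.28 (7 of 16 higher, 0 lower) and ER stress at 0.28 (5 of 11 higher, 0 lower). The tRNA synthetase genes Cars (21.4 and 46.6 CPM, 1.13) and Aars (24.9 and 53.9 CPM, 1.11) were among the highest, with St7 (1.24) and Btf3l4 (1.21). Creb3l2 (-1.24) and the steroid receptor cochaperone gene Fkbp5 (-1.03) were among the lowest. Sst, an interneuron peptide, was at 78.3 and 10.1 CPM (-2.95). At 2000 UMIs the share of astrocyte-like cells with at least 3 S phase genes was 11.2% and 9.42% (-0.25, -1.26 to 0.76), lower where the list was higher. Cells like the oligodendrocyte lineage had the S phase list at -0.43 (1 of 27 higher, 15 lower, percentile 0) and the G2 and M phase list at -0.39 (1 of 22 higher, 12 lower, percentile 0, and -0.80 with no cell filter). Their shares with at least 3 S phase genes at 2000 UMIs were 19.7% and 17.3% (-0.19, -0.87 to 0.49). For G2 and M phase genes they were 42.4% and 34.5% (-0.30, -0.76 to 0.16). Unthinned, 9 WT and 8 FOXM1f/+;Nestin-Cre cells of this class had at least 2 of the 8 dividing genes, so these list medians may rest on few cells. Slc15a2 (30.5 and 61.9 CPM, 1.02) and Cyr61 (29.8 and 59.8 CPM) were higher there. The pseudogene Gm12892 had 0 UMIs in WT and 232 in FOXM1f/+;Nestin-Cre cells of this class, at least 61.2-fold higher. Whether the classes differed from each other was not tested.

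Within neurons, the sterol genes were lower in several classes. Cholesterol synthesis was at -0.38 in thalamic or other neuron-like cells (0 of 15 higher, 8 lower), -0.30 in upper layer-like (0 higher, 6 lower), -0.28 in interneuron-like (0 higher, 5 lower) and -0.19 in striatal-like cells (0 higher, 4 lower). Immature excitatory-like neurons were at -0.11 (0 higher, 0 lower). It was at 0.09 in astrocyte-like, -0.01 in radial glia-like and 0.01 in oligodendrocyte lineage-like cells. Upper layer-like neurons had Nts at 22.0 and 72.8 CPM (1.73, 1.57 to 1.89), the zinc finger gene Tshz2 at 45.3 and 108 CPM, the metallothionein Mt1 at 0.87 and Dkk3 at 0.81. Snhg11 (43.4 and 19.9 CPM, -1.12) and AI593442 (34.9 and 16.3 CPM, -1.09) were lower. These ratios mix clusters 1, 5 and 10, whose shares differed.

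Immature excitatory-like neurons had a G2 and M phase median of -0.24 (2 of 36 higher, 16 lower, percentile 0) and Ccnd1 at 47.7 and 10.7 CPM (-2.15). The share of this class with at least 3 G2 and M phase genes at 2000 UMIs was 47.0% and 44.2% (-0.09, -0.31 to 0.14). At least 2 of the 8 dividing genes were found in 8 WT and 0 FOXM1f/+;Nestin-Cre cells at 2000 UMIs, and in 19 and 17 unthinned. The list median may thus rest on few cells. Mt1 was at 0.84 in these cells, and H2-D1, one of a family of near-identical histocompatibility genes, at 1.17. Interneuron-like cells had Ccnd1 at 357 and 109 UMIs (-1.66), the neuropeptide Cck at 85.4 and 38.2 CPM (-1.16) and Zic1 at 33.8 and 67.4 CPM. Striatal-like neurons had the apolipoprotein Apoe, abundant in astroglia, at 12.6 and 39.5 CPM (1.65), and the interneuron peptides Npy (72.2 and 31.6 CPM, -1.19) and Sst (31.9 and 15.2 CPM, -1.07). The cyclin-dependent kinase inhibitor Cdkn1a was at 27.5 and 13.9 CPM (-0.99). Thalamic or other neuron-like cells had Igfbp4 at 17.8 and 52.7 CPM (1.56) and the synaptic kinase Camk2a at 47.2 and 19.6 CPM (-1.26).

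**Figure D3:**
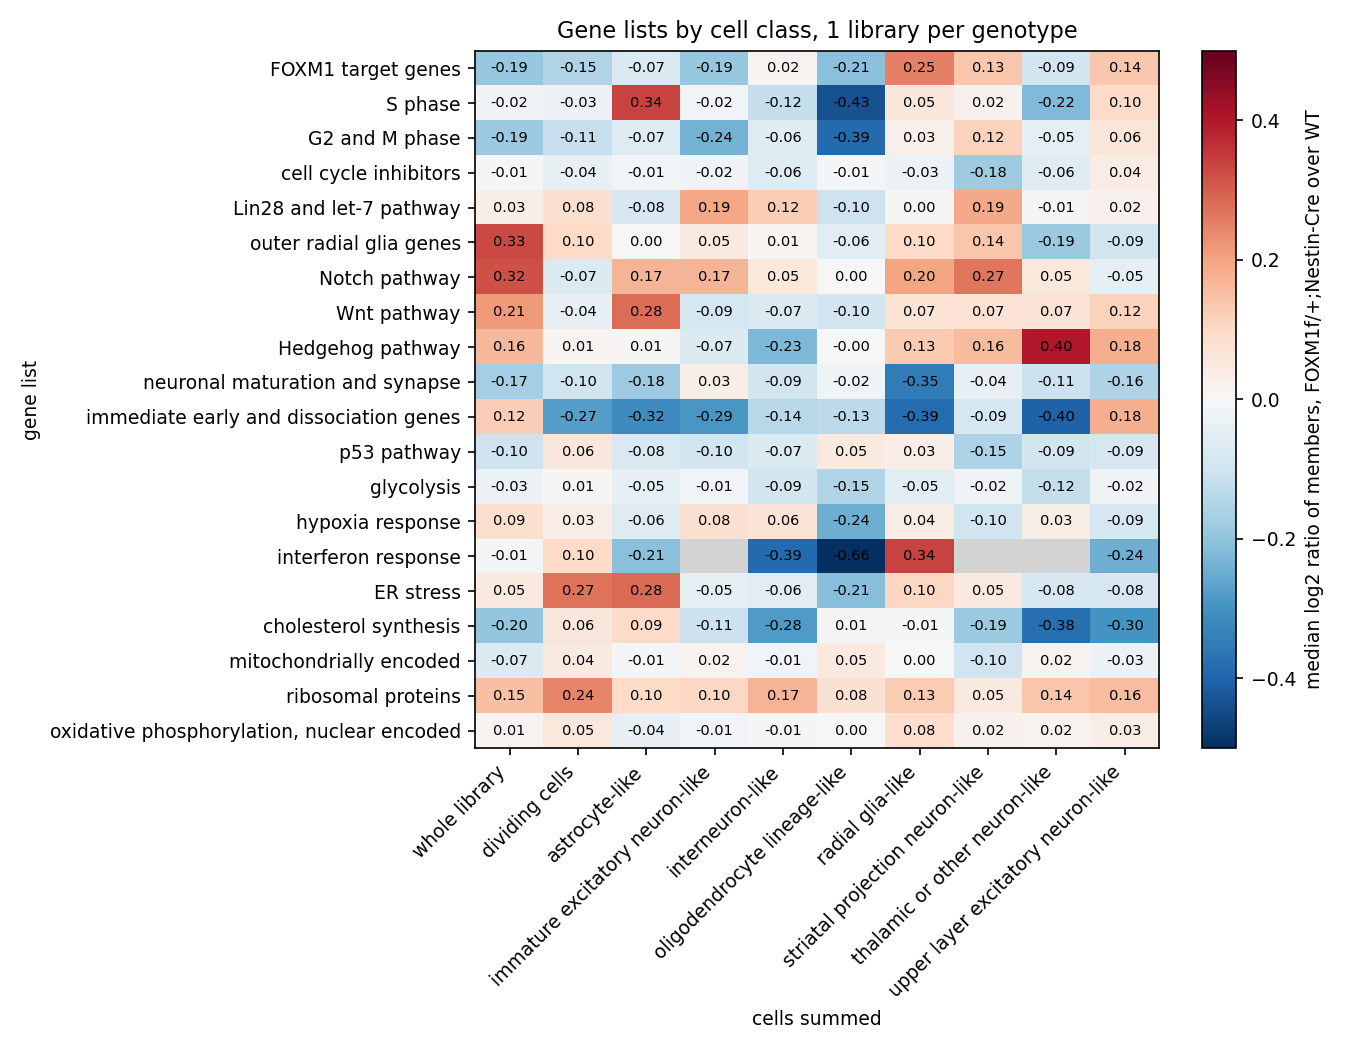
Median log2 ratio (FOXM1f/+;Nestin-Cre over WT, color) of the members of each gene list with at least 20 UMIs (rows) in the whole library and per class (columns), 1 library per genotype; gray marks lists with too few members. Cholesterol synthesis lies between -0.38 and -0.11 in the 5 neuron classes, and ribosomal proteins are above 0 in every column.

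The authors' deposited table of cluster markers lists Foxm1 in 1 of its 25 clusters, cluster 9, with a log fold change of 0.74 and a UMI in 70.9% of the cluster's cells. In the same cluster of the authors' deposited table Top2a had a log fold change of 2.68 and Mki67 of 2.05. Of the 25 FOXM1 target genes, 22 have an entry for that cluster in the authors' deposited table, all 22 above 0. The authors' deposited table gives 0 entries for Lin28a and 0 for Lin28b. Its cluster numbers are the authors' own.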

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

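The settings without cell cycle genes, without the leading genes of the Tshz2 cluster, and with 2 of 8 dividing genes were chosen only after results were seen. No paired analysis was possible because each genotype has 1 library and no test was made. Among named genes 770 ratios under alternatives stayed within their counting interval, 104 moved and 7 reversed; among list medians 803 stayed, 14 moved and 2 reversed, and among shares of cells 108 stayed, 3 moved and 1 reversed. Less stable were list percentiles against unmatched lists (31 moved, 8 stayed) and the 5th and 95th percentiles of ratios (66 moved, 34 stayed), and of cycling ratios 21 moved and 91 stayed. The cause was not tested for the values below, except where the setting itself shows it. With a stricter filter the upper layer-like share ratio was 0.0018. A Tshz2 and Cck cluster (351 WT and 523 FOXM1f/+;Nestin-Cre cells) and a Cbln2 and Grp cluster (342 and 184) then joined the class, and a Nrgn and Rorb cluster (390 and 242) was left unnamed. Their parts in the move were not separated. It was -0.37 with doublets kept and -0.13 without cell cycle genes in clustering. The share of the clusters led by Rorb or Inhba (-0.67) was -0.39 without the leading genes of the Tshz2 cluster. Weighting every cell equally gave Foxm1 -0.27 in the whole library. The sign of mt-Cytb turned to 0.0071 (median-of-ratios scaling), 0.0040 (total without mitochondrial, ribosomal protein and hemoglobin genes) and 0.0084 (cells weighted equally). The 5th and 95th percentiles of all ratios were -0.22 and 0.23 with median-of-ratios scaling, -0.23 and 0.23 with the reduced total, and -0.58 and 0.56 with no minimum CPM, which adds genes with few counts. The FOXM1 target percentile was 0.14 with unmatched lists. With no cell filter the hemoglobin median was -0.94 in the whole library (-1.82 in the main setting). In radial glia-like cells the hemoglobin median reversed from -3.22 to 2.36 and Hbb-bs from -3.25 to 2.40. In striatal-like cells Hba-a1 reversed from 4.83 to -0.23. Also with no filter, the G2 and M phase median was 0.16 in astrocyte-like, 0.071 in interneuron-like, -0.80 in oligodendrocyte lineage-like and 0.17 in upper layer-like cells, the FOXM1 target median 0.14 in interneuron-like cells, and the oxidative phosphorylation median -0.00040 in upper layer-like cells. With doublets kept, Hbb-bs reversed from 1.05 to -0.25 in interneuron-like and from -3.25 to 2.41 in radial glia-like cells. The G2 and M cycling ratio was 0.021 unthinned, -0.15 with at least 5 genes and -0.27 with 2 of 8 dividing genes, and the S phase ratio -0.15 with at least 5 genes. Rescaling shifted all genes by at most 0.04 on the log2 scale. No value was obtained for endothelial-like cells with the stricter filter, for intermediate progenitor-like cells with doublets kept or at resolution 0.5, or for thalamic or other neuron-like cells with no filter, the stricter filter or resolutions 2 and 0.5, where no cluster took the name. Classes under 200 cells are limited by their number of cells: the Cajal-Retzius cell-like ratio rests on 95 and 54 cells.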

Other observations

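The tests of shared sequence and of chromosomes in the first pattern weighed here, and of the cell filter in the second, were chosen only after the result was seen.

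Ccnd1, the G1 cyclin D1, was lower in the FOXM1f/+;Nestin-Cre library in every class compared, though the astrocyte-like interval spans both directions. By point estimate Ccnd1 was lower by more in neurons than in glia. In upper layer-like neurons it was at 29.6 and 8.84 CPM (592 and 138 UMIs, log2 -1.74, interval -2.02 to -1.47), in striatal-like neurons at 31.4 and 7.30 CPM (-2.11, -2.58 to -1.65) and in thalamic or other neuron-like cells at 33.7 and 8.63 CPM (-1.97). In radial glia-like cells it was at 123 and 83.3 CPM (-0.56, -0.77 to -0.36), in cells like the oligodendrocyte lineage at 251 and 205 CPM (-0.29, -0.50 to -0.09) and in astrocyte-like cells at 98.9 and 81.5 CPM (-0.28, -0.63 to 0.07). Whether classes differ was not tested. Zic1, a transcription factor gene of the medial forebrain and septum, was at 41.1 and 69.2 CPM in radial glia-like (0.75), 33.8 and 67.4 CPM in interneuron-like and 21.7 and 46.7 CPM in thalamic or other neuron-like cells (1.11), but at 58.4 and 50.3 CPM in immature excitatory-like neurons (-0.22).

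Genes typical of one class were also counted in others, at levels that differed between libraries. Apoe was at 12220 and 10771 CPM in astrocyte-like cells (-0.18) but at 18.5 and 27.7 CPM in upper layer-like neurons (0.58) and 12.6 and 39.5 CPM in striatal-like neurons (1.65). Sst was at 863 and 896 CPM in interneuron-like cells (0.05), yet at 78.3 and 10.1 CPM in astrocyte-like cells (-2.95). Markers of macrophages (median 0.65), mural cells (0.46) and fibroblasts or meningeal cells (0.52) were higher in the whole FOXM1f/+;Nestin-Cre library, with 5 of 7, 6 of 9 and 5 of 9 members higher past the fold limit set for lists.

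Some genes differed alike in all 4 cell pools tested. Of 10637 genes, 89 were apart past that limit the same way in each pool (41 higher in FOXM1f/+;Nestin-Cre cells and 48 lower) and 18 at least 1.5-fold. A difference of read length or alignment settings was taken to move processed pseudogenes together by 0.2 or more. The median of 83 of them lay 0.071 (0.02 to 0.14) from that of all genes, which argues against such a joint move. Single pseudogenes went far both ways, as Rpsa-ps10 (-5.36) and Gm12892 (7.20) did. A median cannot exclude settings that move pseudogenes in both directions. Reads shared with a near-identical copy are a candidate part of the explanation for the 18. Of these, 72.2% (46.5 to 90.3) share words with another gene against 18.6% of tested genes, as Rpsa-ps10 does with Rpsa and Gm12892 with Ckb. Both libraries were counted on the same features, so shared sequence alone does not say why they differ. Over all 89 only 38 share words, 42.7% (32.3 to 53.6). That is too few for shared reads to play a part in each and too many to exclude them, so there they cannot be told apart. Strain variants may add to this: 18 of the 89 lie on chromosome 17 (GRCm38), which holds 4.62% of tested genes. This count is not separate from shared sequence, since 10 of the 18 on chromosome 17 share words with another gene and 4 of the genes elsewhere have their copy there. Only 6 of 10000 random draws put as many on 1 chromosome, and the 95th percentile of the draws was 13. This argues against a random spread of the 89 genes over chromosomes. The bound set for strain variants was more than any draw, and the highest draw was 21. By that bound strain variants cannot be told apart.

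Fewer FOXM1f/+;Nestin-Cre cells lay in the upper layer-like clusters led by Rorb or Inhba, at a log2 ratio of shares of -0.67. The ratio was -0.39 when the leading genes of cluster 26, led by Tshz2 (161 and 283 cells), were left out of clustering, so its size depends on how cells are divided between clusters. The layer is not settled either: at the finer resolution a cluster led by Nrgn and Rorb (339 and 179 cells) was named deep layer-like, as was a cluster led by Nrgn and Cbln2 (323 and 183 cells) with no cell filter. Weighting both libraries to the same 10 depth classes gave -0.89 (-1.02 to -0.73). The FOXM1f/+;Nestin-Cre library was the deeper one (median 8936 against 7805.5 UMIs in WT), and these clusters lay mostly in the deepest classes. Weighting could thus be foreseen to lower the ratio, so it does not decide on UMI depth. Cells of these clusters were also deeper in the FOXM1f/+;Nestin-Cre library. Median UMIs in WT and FOXM1f/+;Nestin-Cre cells were 17042 and 19351.5 in cluster 1, and 12979 and 15501.5 in cluster 5. A depth class can therefore hold unlike cells of the libraries. For clusters led by Rorb or Inhba whatever their name, the ratio was -0.54 (-0.71 to -0.37) under the stricter filter and -0.69 (-0.89 to -0.50) with none. This argues against the cell filter as the cause for clusters so led. These are not all the same upper layer-like clusters, since a Nrgn and Rorb cluster was unnamed under the stricter filter. Sampling of another part of the cortex may contribute and cannot be told apart: in radial glia-like cells the median of 8 medial genes minus that of 7 lateral genes was -0.00013 (-0.51 to 0.25), and medial genes went both ways, with Wnt8b at -0.95 and Zic5 at 0.21. Genotype stays open as well, with 1 library each.

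As a list, FOXM1 target genes were slightly lower in the dividing cells of the FOXM1f/+;Nestin-Cre library, at a median of -0.15 in cluster 9. Few members passed the fold limit set for lists, and many members also define the cluster. Another mix of dividing lineages is argued against as the whole cause, which needed a value above -0.05, since the medians within lineages, weighted by cells, came to -0.15 (-0.20 to -0.08), with -0.18 in cells with GABA lineage genes (238 and 175 cells) and -0.10 in astroglial ones (179 and 137 cells). Scaling, in which higher ribosomal protein genes lower all others, accounted for a small part. Leaving ribosomal protein, mitochondrial and hemoglobin genes out of the total raised every gene of cluster 9 by 0.028 on the log2 scale. The median was then -0.12. Its interval over genes, -0.14 to -0.04, crosses the same bound of -0.05, so by that bound the test could not decide. The genotype is an untested alternative.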
